A study of Mus musculus with 576 samples.

How the data were processed

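Single-cell transcriptomes were measured in cells from the liver of embryonic day 14.5 mice of the C57/Bl6J strain. Per the labels' protocols, fetal liver was depleted with antibodies against CD3e, CD45R, Ly-6G, CD11b, Ter119, Sca-1, CD16/32 and CD41. The rest was stained for CD117 (the product of Kit), CD71 (Tfrc) and CD24 and sorted for cells enriched in burst forming unit-erythroid (BFU-E), the early committed progenitor of the red cell lineage. This sort came before culture and was shared by all groups. The sorted cells were cultured for 24, 48 or 72 hours with stem cell factor at 100 ng/mL, insulin-like growth factor 1 at 40 ng/mL and erythropoietin at 2 U/mL, without or with the synthetic glucocorticoid dexamethasone at 100 nM. Polyadenylated RNA of single cells was sequenced from 6 plates of 96 wells, 1 plate for each combination of day and treatment.

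The deposited table holds whole-number counts per gene and well. Per the submitters' processing notes, STAR 2.4, featureCounts and the mouse genome build GRCm38 were used for these counts. The annotation release, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Reads from a gene and its antisense partner, from overlapping genes or from near-identical copies may therefore be exchanged or lost, which concerns the globin pairs Hba-a1 and Hba-a2 and Hbb-bs and Hbb-bt, the ferritins Fth1 and Ftl1, Clca3a1 and Apol11b among the genes named. No molecular identifiers are stated, so a count is a read, amplified copies are counted again, and every Poisson or binomial interval covers counting error only. Of 576 value columns, 575 matched the labels of a well, and 1 column that did not match was not used. The header line has 1 empty cell more than the lines of values, after the name of the gene column. Leaving it out gives as many names as value columns, and this reading was used. A reading shifted by 1 column would give every well to another plate. The variance of the mean log10 total per index pair was 0.0213 for the reading used and 0.019 for the shifted one, a modest difference that does not settle it alone. In the reading used, the glucocorticoid-induced genes Mt2, Fkbp5, Per1 and Tsc22d3 were each higher in every dexamethasone plate than in every control plate, which a shift by 1 column would break. No row lacked a gene identifier. The identifiers were matched to the GENCODE vM21 annotation of GRCm38, which gave coordinates and gene types for 49326 of 49466 genes. Symbols came with the deposited counts. The 153 rows that shared 76 symbols were kept apart.

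Thresholds, tests, gene lists and the rule for named genes were fixed before the data were examined. A well was kept as a cell with at least 50000 gene counts, at least 1500 genes with a count and at most 20% of counts on mitochondrially encoded genes. This kept 563 cells and removed 12 wells, 10 for low counts and 2 for mitochondrial counts alone. Kept cells held between 66140 and 3757116 counts with a median of 1092431. No doublet caller was run, since wells were filled from a sorter and not by droplets. Cells of a plate are not replicates of a treatment, so counts were summed over the kept cells of each plate, giving 6 sums of 88158683 to 116554686 counts on the tested genes. Nothing in the labels says whether the plates came from separate animals or cultures. P-values therefore measure the spread between these plates, which may be technical. No day and treatment has a second plate, so this spread also holds any change of the dexamethasone difference over the days. The tests cannot separate such a change from plate effects. A gene whose difference varies with the day can thus miss the threshold, and a missing call does not show that a difference is absent.

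The main test was the quasi-likelihood test of edgeR 4.0.16 on the 6 sums, with day and dexamethasone as additive terms. It left 2 residual degrees of freedom, with TMM scaling, the filterByExpr filter (20040 genes), Benjamini-Hochberg adjustment over genes and a threshold of 0.05. The coefficients tested were dexamethasone over the 3 days, day 3 against day 1 and day 2 against day 1. The standard error (SE) of a log2 fold change was taken as its size divided by the square root of the F statistic. Within a day there is 1 plate per treatment, so differences are log2 ratios of TMM-scaled CPM (counts scaled by library size) with a prior count of 2 and no test. Exact Poisson intervals of a plate's CPM and exact Clopper-Pearson intervals of shares of cells are at 95% confidence. For a share of 0 the limit that 3 cells would give is also stated. A plate without a count of a gene allows up to 3 counts, equal to 0.0249 to 0.0335 CPM depending on the plate.

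A set of 25 gene lists was tested with camera of limma 3.58.1 at a preset correlation of 0.01 between genes and again with an estimated correlation, adjusted over the lists of each contrast. The second form rests on the 2 residual degrees of freedom of the fit, so it can lose a call whatever the correlation. The lists cover glucocorticoid receptor targets, early progenitor genes, erythroid transcription factors, globins, heme synthesis and iron handling, red cell membrane and late erythroid genes, and erythropoietin and STAT5 targets. Further lists cover S phase, G2 and M phase, cyclin-dependent kinase inhibitors and quiescence, MYC and ribosome biogenesis, cholesterol synthesis, glycolysis and hypoxia, p53 targets, amino acid and unfolded protein stress, immediate early and heat shock genes, interferon response and mitochondrially encoded genes. The remaining lists are markers of megakaryocytes, mast cells and basophils, neutrophils and monocytes, lymphoid cells, macrophages, hepatocytes, and endothelial and stromal cells. The erythroid progression score of a cell was the mean log2(CPM + 1) of the globin, heme and late erythroid lists minus that of the early progenitor list. Zfp36l2, 1 of the 22 early genes in the score, is also on the list of glucocorticoid receptor targets. The score is thus not wholly independent of that list. Scores of S phase and of G2 and M phase were means of their lists. Differences of plate medians over the 3 days were tested with an exact two-sided sign-flip permutation test, which cannot go below 0.25. To compare shares of cells with a count across depths, cells were also thinned to 620000 counts, which 509 cells reached. A cell was counted for another lineage with at least 3 of its markers at 10 CPM or more.

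Genes were named by rule. Since fewer than 10 genes passed the threshold for dexamethasone or for day 3 against day 1, the rule took the 10 higher and 10 lower genes with the largest smallest log2 ratio over the 3 days, or over both treatments for time, at a mean of at least 10 CPM. Within a day it took the 4 highest and 4 lowest ratios among genes with at least 50 CPM in the higher plate and a count in at least 25% of its cells. Up to 4 members per list, by mean CPM where none passed the threshold, and Nr3c1, Kit, Gata1, Gata2, Klf1, Epor, Hbb-bt, Hba-a1, Fkbp5, Tsc22d3, Per1 and Zfp36l2 were added. Predicted genes and pseudogenes were not named but were counted. The values of 1 gene that the rule names are not reported.

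The test was checked on simulated counts with 200 changed genes, drawn from the means, depths and estimated dispersions of these plates. Each changed gene had the same fold on all 3 days. The shares called may therefore not carry over to genes whose difference changed with the day. For dexamethasone over 18650 genes in the fit, edgeR called 6 of 66 genes changed 2-fold, 24 of 60 changed 4-fold and 38 of 61 changed 16-fold, with 10 of 18463 unchanged genes called. DESeq2 1.42.0 called 18, 30 and 49 of them, with 155 unchanged genes called, more than the changed genes it called. Over 4329 genes at a mean of at least 50 CPM, edgeR called 53 of 67, 66 of 67 and 66 of 66, with 15 of 4129 unchanged genes called.

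The alternatives chosen beforehand were RLE size factors, DESeq2, no filter on low counts, thinned cells, all wells, a stricter cell filter (200000 counts and 3000 genes), no mitochondrially encoded genes, each day left out in turn, no day term, other score settings and other marker thresholds. Filters at a mean of 5, 10 and 50 CPM for the number of genes, robust estimates, and the removal of 55 cells with at least 2 neutrophil or monocyte markers were added after the data had been seen. Python 3.11.15 and R 4.3.3 were used.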

Results

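The data are counts per gene in single cells from cultures of BFU-E enriched mouse fetal liver cells, sampled on days 1, 2 and 3 without dexamethasone (control) or with it. The comparisons the design implies are dexamethasone against control, which asks how a glucocorticoid alters the transcriptome of erythroid progenitors, and later against earlier days. The kept cells numbered 94, 96 and 93 on the control plates of days 1, 2 and 3, and 94, 92 and 94 on the dexamethasone plates. Plates held 88158683, 113125231 and 116554686 counts on the tested genes for control and 115750771, 111631848 and 100181043 for dexamethasone. The median count per cell ran from 922603 on control day 1 to 1244026 on control day 3. A median control cell had 8119, 7556 and 6961 genes with a count on days 1 to 3, and a dexamethasone cell 8924, 8829 and 8520. At 620000 counts per cell these medians were 7855, 7298 and 6142 against 8350, 8330 and 8056. The median share of mitochondrially encoded counts was 3.91%, 3.47% and 3.38% in control and 3.93%, 4.61% and 5.69% with dexamethasone. Plate, sequencing lane and group coincide, so a plate difference and a treatment difference within a day cannot be separated, and single plates have no replicates.

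Cells cultured with dexamethasone carried fewer transcripts of the red cell programme on each day. Hbb-bt, an adult beta globin gene, stood at 26.8, 1034 and 2274 CPM on control days 1, 2 and 3 and at 3.83, 44.5 and 397 CPM with dexamethasone. Hba-a1, an alpha globin gene, stood at 41.98, 2161 and 4160 CPM in control and at 9.75, 113.5 and 1291 CPM with dexamethasone. Slc4a1, the anion exchanger of the red cell membrane, reached 2595 and 3376 CPM on control days 2 and 3. With dexamethasone it had 0.0868 CPM from 10 counts on day 2 and 444.5 CPM on day 3. Tfrc, the transferrin receptor that brings iron into the cell, was at 1337, 3905 and 5180 CPM in control and 753 (Poisson interval 748 to 758), 1429 and 1591 CPM with dexamethasone.

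Over the 3 days, with 3 plates per treatment, none of 20040 genes passed an adjusted p of 0.05 for dexamethasone in edgeR. The count at an unadjusted p under 0.05 was 2070, the smallest adjusted p was 0.457, and DESeq2 called 1258 genes, 501 higher and 757 lower. Among 4329 genes at a mean of at least 50 CPM, a filter chosen after the data were seen, edgeR called 39, of which 18 were higher and 21 lower, with Hbb-bt, Trim10, Tfrc and Dmtn among the lower and Mt1, Mt2, Tsc22d3, Gata2 and Acp5 among the higher. The values that follow are sizes in these plates unless a test is named with them.

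All 6 measured globins were lower in sign over the 3 days together, with a median log2 fold change of -2.85, and 4 fell when adjusted over the list alone. Hbb-bh1 and Hbb-y were low, at means of 1.39 and 1.04 CPM. Hbb-bh1 had a log2 fold change of -1.72 (SE 3.70) and was higher on day 1, at 0.374 CPM against no count in control. Hbb-bt had a log2 fold change of -3.27 (SE 0.49, edgeR adjusted p = 0.457), lower on 3 of 3 days, and Hba-a1 -2.65 (SE 0.60, edgeR adjusted p = 0.457), also lower on 3 of 3 days. Camera gave the globins an adjusted p of 5.62e-05 at the preset correlation, against an adjusted p = 0.677 with an estimated correlation. The 4 abundant globins are near-identical pairs that featureCounts may split, so the share of each copy is uncertain. Of 22 genes of heme synthesis and iron handling, 21 were lower in sign with a median of -0.83, and 3 fell when adjusted over the list alone. Fech, the enzyme that inserts iron into heme, had log2 ratios of -0.10, -1.52 and -1.46 on days 1, 2 and 3, while the ferritin heavy chain Fth1 had 0.61, 0.17 and -0.44. The camera adjusted p was 3.77e-08, and adjusted p = 0.677 with an estimated correlation. Of 29 red cell membrane and late erythroid genes, 27 were lower in sign with a median of -0.83. Adjusted over the list alone, 8 fell and 1 rose. Car2, a carbonic anhydrase, had a log2 fold change of -0.73 (SE 0.21) and Prdx2, a peroxidase of red cells, -1.09 (SE 0.38). The camera adjusted p of this list was 7.6e-10, and adjusted p = 0.677 with an estimated correlation. Of 20 erythroid transcription factors 5 were positive in sign, with a median of -0.38 and none past the list's own threshold. Klf1, which activates adult globin genes, had log2 ratios of -0.50, -1.41 and -0.43, and Gata1, the master regulator of the lineage, -0.10, -0.85 and -0.86. The camera adjusted p was 0.00169, and adjusted p = 0.677 with an estimated correlation.

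**Figure D1:**
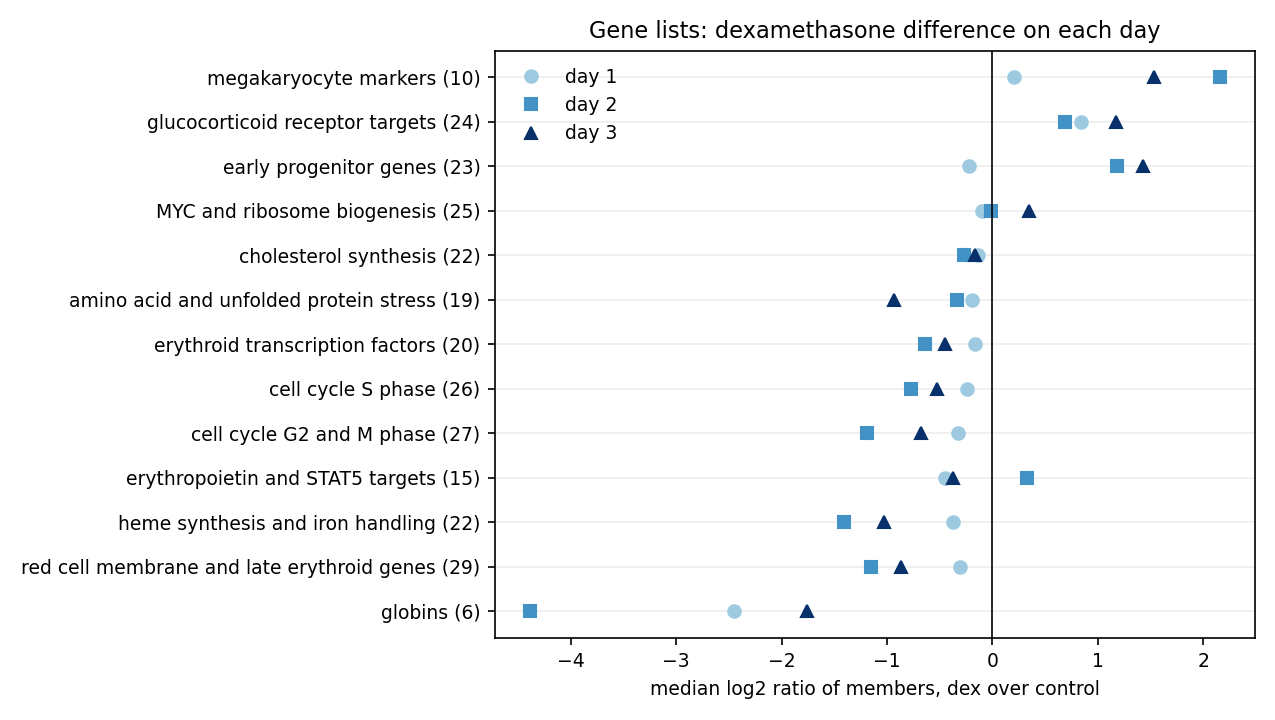
Median log2 ratio of the members of 13 gene lists, dexamethasone over control, on days 1, 2 and 3 (points), with the number of measured members in brackets and 1 plate per point and treatment. Globins lie at -2.45, -4.39 and -1.76 and glucocorticoid receptor targets at 0.84, 0.69 and 1.17. Without the prior count, and with plates at 0 set to the floor of 3 counts, the globin median on day 2 is -5.02.

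Genes that glucocorticoids are known to induce were higher with dexamethasone. Of these, Mt2, Fkbp5, Per1 and Tsc22d3 also served to choose how the header was read, so their direction is not independent of that choice. Fkbp5, a co-chaperone of the glucocorticoid receptor, stood at 21.03, 16.6 and 12.8 CPM in control and 38.9, 44.3 and 26.8 CPM with dexamethasone. Tsc22d3, which encodes the glucocorticoid-induced leucine zipper, stood at 23.4, 24.8 and 37.6 CPM against 81.6, 72.8 and 74.7 CPM. Per1, a clock gene with a glucocorticoid response element, stood at 20.9, 23.9 and 12.8 CPM against 50.9, 80.8 and 43.6 CPM. Zfp36l2, an RNA-binding protein needed for BFU-E self-renewal, stood at 16.2, 6.85 and 8.04 CPM against 40.2, 55.5 and 31.8 CPM. Of 24 measured glucocorticoid receptor targets 17 were positive in sign with a median of 1.11. Adjusted over the list alone 9 rose and 1 fell. Camera gave an adjusted p of 0.00068 at the preset correlation, against an adjusted p = 0.677 with an estimated correlation, which was -0.01. The metallothionein genes, which encode metal-binding proteins, showed Mt1 at a log2 fold change of 2.17 (SE 0.39) and Mt2 at 5.04 (SE 0.78), both higher on 3 of 3 days. Tgm2, a transglutaminase on the same list, had log2 ratios of 0.78, -1.72 and -0.76. Nr3c1, the glucocorticoid receptor itself, had log2 ratios of 0.27, 0.61 and 0.44.

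The progenitor receptor Kit, through which stem cell factor signals, was at 314, 139 and 49.5 CPM in control and at 489, 738 and 279 CPM with dexamethasone. A Kit count was found in 48.4% of control day 3 cells (interval 37.9 to 59) and in 94.7% of dexamethasone day 3 cells (88 to 98.3); in thinned cells these shares were 40.4% and 95.3%. Gata2, a transcription factor of early progenitors, had a log2 fold change of 1.32 (SE 0.18, edgeR adjusted p = 0.457) and was higher on 3 of 3 days. The 23 early progenitor genes had a median of 0.92, with 17 positive in sign and 1 that rose when adjusted over the list alone. Camera gave an adjusted p of 0.0147, against an adjusted p = 0.707 with an estimated correlation. Abundant members such as Adgrg1, Cd44 and Lyl1 had log2 fold changes of -0.15, -0.23 and -0.01. The median was -0.22 on day 1, 1.18 on day 2 and 1.43 on day 3. Without the cells that carried at least 2 neutrophil or monocyte markers these medians were 0.20, 0.74 and 0.02. Epor, the erythropoietin receptor, had log2 ratios of 0.17, -0.60 and -0.14.

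**Figure D2:**
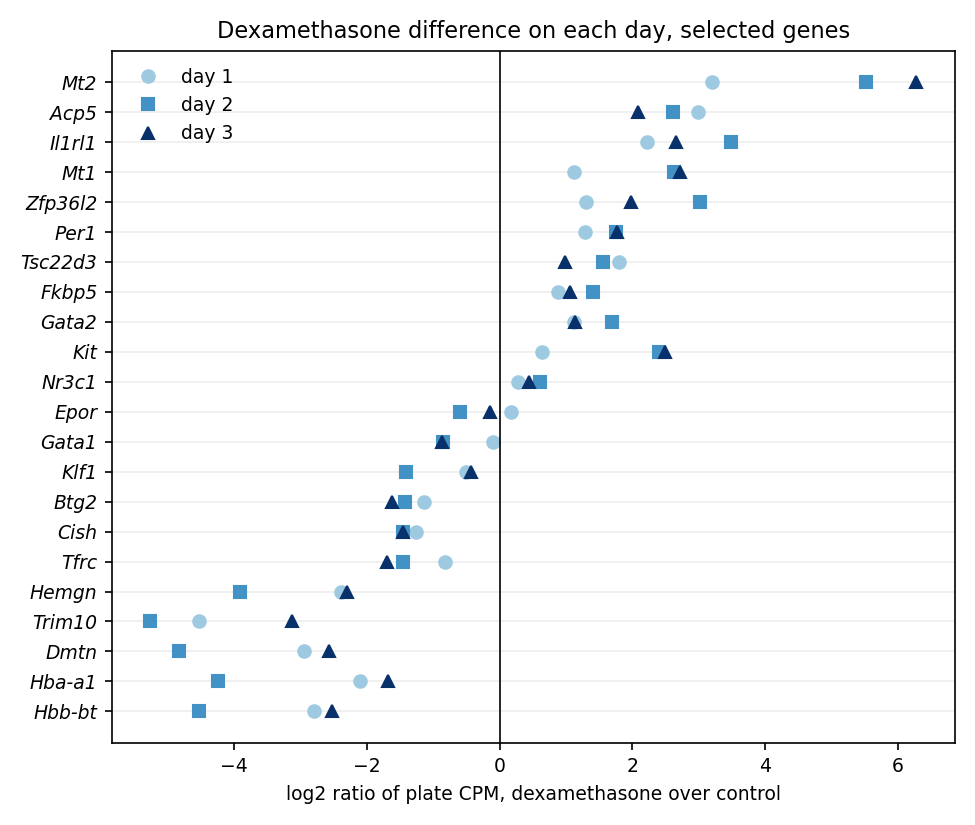
Log2 ratio of plate CPM, dexamethasone over control, for 22 of the named genes, selected after their values were seen, on days 1, 2 and 3 (points), with 1 plate per treatment and day and no error bars. Hbb-bt lies at -2.80, -4.54 and -2.52 and Mt2 at 3.21, 5.52 and 6.28.

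The genes whose smallest daily log2 ratio was largest included Il1rl1, the receptor for interleukin 33, at 6.12, 12.8 and 10.4 CPM in control and 28.8, 143.2 and 66.1 CPM with dexamethasone. Acp5, a tartrate-resistant acid phosphatase, was at 6.49, 22.2 and 48.9 CPM against 51.5, 136.5 and 208 CPM. Nt5e, an enzyme that forms adenosine outside the cell, had log2 ratios of 4.05, 3.86 and 1.94, and Rec8, a cohesin subunit of meiosis, 3.25, 2.63 and 5.32. Apoa1, the main protein of high-density lipoprotein, was at 3.75, 60.4 and 3.67 CPM with dexamethasone. In control it was at 0.212 and 0.0835 CPM on days 1 and 2 and had no count on day 3, which allows up to 0.0267 CPM. The other genes of this kind were Clca3a1, Arhgef10l, Ehbp1 and Fkbp11, with smallest daily log2 ratios of 3.00, 2.19, 2.14 and 2.04. Among lower genes, Trim10, which acts in terminal erythroid differentiation, had log2 ratios of -4.53, -5.27 and -3.13, and Dmtn, an actin-binding protein of the red cell membrane, -2.95, -4.83 and -2.57. Tmcc2 had -2.58, -6.55 and -7.86, Slc22a4, a carnitine and ergothioneine transporter, -3.30, -5.45 and -3.29, and Prss50, a serine protease, -2.89, -6.17 and -5.65. Tinagl1, Gstt1, Oasl2, Dusp8 and Slc4a1 were also lower on each day, but each had at least 1 dexamethasone plate without a count. Oasl2, an interferon-inducible gene, was at 148.9 CPM on control day 3 and 1.86 CPM with dexamethasone, and 33.1% of the former came from 1 cell.

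Genes of the cell cycle were lower with dexamethasone in the plate sums. Of 26 S phase genes none was positive in sign, the median was -0.50, and 15 fell when adjusted over the list alone. Rrm2, a subunit of ribonucleotide reductase, had log2 ratios of -0.27, -1.25 and -1.27, and the replication helicase subunit Mcm6 -0.52, -0.70 and -0.47. Of 27 genes of G2 and M phase 1 was positive in sign, the median was -0.76, and 15 fell when adjusted over the list alone. Top2a, the topoisomerase of dividing cells, had a log2 fold change of -0.92 (SE 0.19). The camera adjusted p was 9.29e-09 for S phase and 1.52e-10 for G2 and M phase, and for both adjusted p = 0.677 with an estimated correlation. Plate medians of the S phase score per cell differed by -0.08, -0.97 and -0.10 on days 1, 2 and 3, and of the G2 and M phase score by -0.24, -0.65 and -0.19. For S phase these were -0.18, -1.02 and -0.32 without the cells with neutrophil or monocyte markers, and -0.07, -0.94 and -0.18 in thinned cells. Both gave an exact two-sided sign-flip permutation p of 0.25 (n = 3 days), the smallest possible. On day 3 the low end of the S phase score went the other way. Its 10th percentile was 2.63 in control and 5.04 with dexamethasone, and its lower quartile 5.76 and 6.25. For G2 and M phase the 10th percentile was 2.67 and 3.37, while the lower quartile was 4.94 and 4.71. Control day 3 thus held cells with lower S phase scores, which sums and medians do not show. The cyclin-dependent kinase inhibitors and quiescence genes had a median of -0.58 with 4 of 13 positive in sign and 1 that fell when adjusted over the list alone, and a camera adjusted p of 0.0819. Among them Btg2, an antiproliferative gene, had -1.15, -1.42 and -1.61, and Txnip, an inhibitor of thioredoxin, 0.69, 1.68 and 0.81.

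Targets of erythropoietin and STAT5 moved in both directions. Of 15 measured members 5 fell and 2 rose when adjusted over the list alone, with a median of -0.77 over the days and a camera adjusted p of 0.105. The median of day 2 alone was 0.33. Cish, a feedback inhibitor of cytokine signalling, had log2 ratios of -1.26, -1.46 and -1.45, and Bcl2l1, which encodes the survival protein BCL-XL, -0.45, -0.82 and -2.75. The amino acid and unfolded protein stress genes had a median of -0.51 with 5 of 19 positive in sign. Their camera adjusted p was 0.00197, and adjusted p = 0.677 with an estimated correlation. Asns, asparagine synthetase, had -0.19, -0.76 and -0.59. Cholesterol synthesis had a median of -0.18 over 22 genes and a camera adjusted p of 0.0456, against an adjusted p = 0.685 with an estimated correlation. Camera made no call for MYC and ribosome biogenesis (median 0.13, camera adjusted p 0.424), glycolysis and hypoxia (0.00, 0.886), p53 targets (0.00, 0.82), immediate early and heat shock genes (0.10, 0.591), interferon response (-0.12, 0.0982) or mitochondrially encoded genes (0.16, 0.845). Adjusted over the list alone, 1 glycolysis and hypoxia gene rose and 1 immediate early gene fell, while no member of the other 4 of these lists passed. Jun, an early response transcription factor, had a log2 fold change of -1.66 (SE 0.16). For the immediate early genes the camera direction was down while median and mean were positive, for p53 targets it was down with a mean of 0.01, and for macrophage markers it was down with a median of 0.39. For lymphoid markers it was up with a mean of -0.34.

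Scored per cell, progression along the red cell programme was lower with dexamethasone on each day. Median scores were 3.19, 5.93 and 6.57 on control days 1, 2 and 3 and 2.35, 2.77 and 4.11 with dexamethasone. The differences of -0.85, -3.17 and -2.46 had a mean of -2.16 (SD 1.19, n = 3 days) and an exact two-sided sign-flip permutation p of 0.25, the smallest that 3 days allow. The part of the score from late erythroid genes differed by -0.47, -1.88 and -1.19, and the part from early progenitor genes by 0.34, 1.33 and 1.07. Scores over 4.38, the 90th percentile of control day 1 cells and a value chosen after the data were seen, were found in 10.6%, 68.8% and 88.2% of control cells. With dexamethasone they were found in 0 of 94 cells on day 1, which allows up to 3.19% by 3 cells (Clopper-Pearson limit 3.8%), in 2.2% on day 2 (interval 0.3 to 7.6) and in 41.5% on day 3 (31.4 to 52.1). Of the day 3 dexamethasone cells 24 lay within 0.5 of that value.

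**Figure D3:**
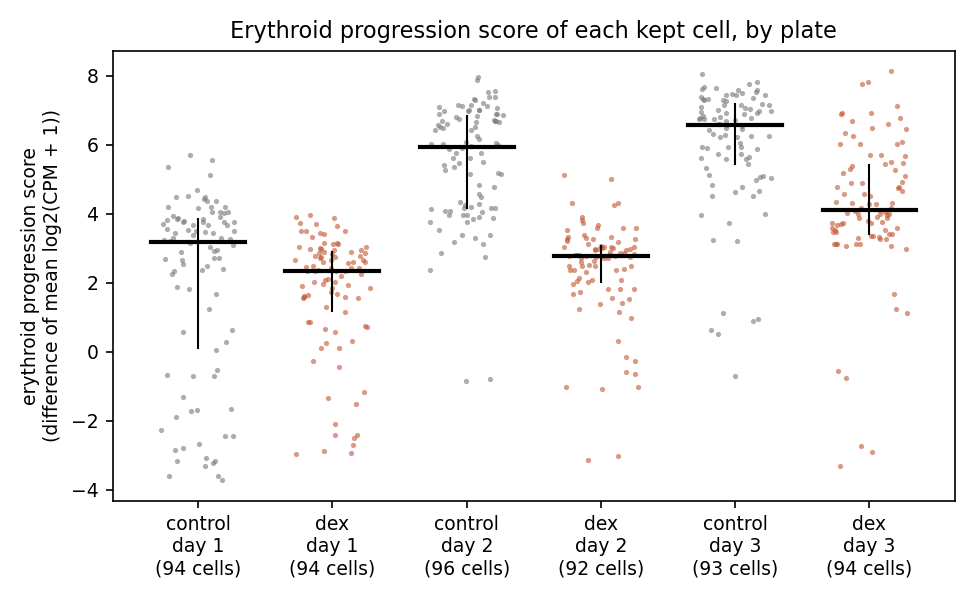
Erythroid progression score of every kept cell (points) on each of the 6 plates, with the plate median (thick bar) and the quartiles (thin line); the score is a difference of mean log2(CPM + 1) values. Control medians lie at 3.19, 5.93 and 6.57 and dexamethasone medians at 2.35, 2.77 and 4.11.

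With days in culture the red cell genes were higher in both treatments. From day 1 to day 3 Hbb-bs, a beta globin gene, went from 258.5 to 9322 CPM in control and from 21.3 to 3292 CPM with dexamethasone. Trim10 went from 7.32 to 695 CPM and from 0.299 to 79.5 CPM, and Car2 from 1017 to 4315 CPM and from 809 to 2844 CPM. Kit went from 314 to 49.5 CPM in control and from 489 to 279 CPM with dexamethasone. Of 20040 genes none passed an adjusted p of 0.05 for day 3 against day 1 or for day 2 against day 1 in edgeR. Unadjusted p-values under 0.05 numbered 2907 and 2446, and DESeq2 called 2061 and 1550. At a mean of at least 50 CPM edgeR called 549 (326 higher, 223 lower) and 233 (159 higher, 74 lower).

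Among gene lists for day 3 against day 1, 25 of 29 red cell membrane and late erythroid genes, 14 of 22 heme and iron genes and 4 of 6 globins rose when adjusted over the list alone. Their medians were 1.63, 1.45 and 6.49, and their camera adjusted p-values were 3.15e-12, 2.51e-07 and 1.7e-05. For each of these the test gave adjusted p = 0.573 with an estimated correlation. Of 18 p53 targets 11 rose when adjusted over the list alone, with a median of 1.64 and a camera adjusted p of 4.95e-08, against an adjusted p = 0.573 with an estimated correlation. Cdkn1a, the cyclin-dependent kinase inhibitor p21, had a log2 fold change of 2.71 (SE 0.21, edgeR adjusted p = 0.21), higher on day 3 in both treatments. Ccng1, a cyclin induced by p53, had 1.61 (SE 0.19) and Mdm2, the ubiquitin ligase of p53, 1.42 (SE 0.19). Of 25 genes of MYC and ribosome biogenesis 22 fell when adjusted over the list alone, with a median of -0.79. The nucleolar proteins Ncl and Npm1 had -0.94 (SE 0.13) and -0.59 (SE 0.14). The camera adjusted p was 5.77e-09, and adjusted p = 0.573 with an estimated correlation. Early progenitor genes had a median of -1.80 with 2 of 23 positive in sign and a camera adjusted p of 0.000319, against an adjusted p = 0.608 with an estimated correlation. Immediate early and heat shock genes had a median of -0.60, with 6 of 20 that fell when adjusted over the list alone, and a camera adjusted p of 0.000384, against an adjusted p = 0.573 with an estimated correlation. Of 13 cyclin-dependent kinase inhibitors and quiescence genes 3 rose when adjusted over the list alone, with a median of 0.91 and a camera adjusted p of 0.00756, against an adjusted p = 0.573 with an estimated correlation. G2 and M phase genes had a median of 0.37 and a camera adjusted p of 0.0133, against an adjusted p = 0.803 with an estimated correlation, while the median score per cell was lower on day 3 than on day 1, by -0.55 in control and -0.49 with dexamethasone. Cholesterol synthesis had a median of 0.33 and a camera adjusted p of 0.0314, against an adjusted p = 0.632 with an estimated correlation. Fos, also an early response factor, had a log2 fold change of -3.51 (SE 0.32), from 202 to 14.8 CPM in control and from 96.2 to 10.5 CPM with dexamethasone.

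Other genes named for time were Apol11b, Hba-a2 and Hbq1b, higher on day 3, and Ehd3, Fam174b, Tmem176b, Fkbp11 and Slc45a3, lower on day 3. Ehd3, a protein of endosome traffic, went from 42.4 to 1.89 CPM in control and from 30.1 to 1.40 CPM with dexamethasone. A single cell held 99.2% of the Lcn2 counts on control day 3, 57.8% of those of S100a8 on the same plate, 72.3% of those of Ccr9 on control day 1, and 49.7% of those of Ighm on control day 2. Timp3, an inhibitor of metalloproteinases, was at 17.2 CPM on control day 1 and 8.53 CPM on dexamethasone day 1. On day 3 it had 0.00892 CPM from 1 count in control and no count with dexamethasone.

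Within day 1, the highest ratios with dexamethasone were those of Mt2, Acp5, Anxa2 and Fkbp11, at log2 3.21, 2.98, 2.42 and 2.04. The lowest were those of Hbb-bs, Hemgn, Atp1b2 and Mpo, at -3.60, -2.39, -2.34 and -2.11. Hemgn is a nuclear protein of blood cell precursors and Anxa2 a calcium-dependent membrane-binding protein. Mpo, the myeloperoxidase of granulocytes, was higher by 0.72 with dexamethasone once the cells with neutrophil or monocyte markers were left out. Mpo is itself 1 of those markers, and the removal took 17 control and 10 dexamethasone cells of day 1. The turn in sign is thus in part fixed by the removal. Within day 2, Hdc, the enzyme that forms histamine, was at 691.6 CPM with dexamethasone and 2.94 CPM in control. A count of it was found in 96.7% (interval 90.8 to 99.3) and 8.3% (3.7 to 15.8) of cells, and in 92% and 7.7% of thinned cells. Cpa3, a mast cell protease, Apoa1 and Pf4, a platelet chemokine, were at 106.5, 60.4 and 105.3 CPM with dexamethasone, and 1 cell held 79.3% of the Cpa3 and 62.9% of the Pf4 counts. Slc4a1 was lowest, followed by Tinagl1, Tmcc2 and Hba-a2, with a Slc4a1 count in 4.3% (1.2 to 10.8) of dexamethasone cells and 99.0% (94.3 to 100) of control cells. Within day 3, Mt2, Arhgef10l, Rec8 and the lipoprotein lipase gene Lpl had the highest ratios, at 6.28, 5.59, 5.32 and 4.56. Tmcc2, Oasl2, Slfn14 and Dapk2 had the lowest, at -7.86, -6.30, -4.91 and -4.77.

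Markers of other lineages were present, after a depletion before culture that used CD41 (the product of Itga2b), Ly-6G, CD11b and CD16/32. At least 3 megakaryocyte markers at 10 CPM were found in 43.6%, 30.2% and 19.4% of control cells on days 1, 2 and 3 and in 45.7%, 54.4% and 66% of dexamethasone cells. The intervals were 11.9 to 28.9 and 55.5 to 75.4 on day 3. Many of these cells lay at the threshold: of those counted on days 1, 2 and 3, 21 of 41, 15 of 29 and 13 of 18 control cells and 16 of 43, 36 of 50 and 45 of 62 dexamethasone cells had exactly 3 markers. Cells with 7 or more numbered 7, 0 and 0 in control and 12, 6 and 1 with dexamethasone, and Pf4 was at 10 CPM in 2 of the 62 cells. With dexamethasone on days 2 and 3, most cells with exactly 3 markers carried Itga2b and Gp5, often with Gp1ba or Gp9. Their progression scores spread over much of the range of their plates. The count alone thus does not show cells of the megakaryocyte lineage. Itga2b was at 105, 44.4 and 50 CPM in control and 151, 175 and 151 CPM with dexamethasone, and the platelet integrin gene Itgb3 at 54.3, 1.66 and 9.23 CPM against 99.7, 97.6 and 47.4 CPM. The megakaryocyte list had a median of 1.64, with 8 of 10 members positive in sign, and a camera adjusted p of 0.03, against an adjusted p = 0.677 with an estimated correlation. Cells with at least 3 neutrophil or monocyte markers at 10 CPM numbered 13, 0 and 9 on control days 1, 2 and 3 and 9, 4 and 6 with dexamethasone, and at any count 26, 0 and 48 against 17, 14 and 24. Cells with at least 2 at 10 CPM, the rule used for leaving cells out, numbered 17, 0 and 11 on control days 1, 2 and 3 and 10, 6 and 11 with dexamethasone, of 92 to 96 cells per plate. These last held 15.3% of the counts of control day 1 and none on control day 2, where 0 of 96 cells allows up to 3.12% by 3 cells (Clopper-Pearson limit 3.77%). Mpo was at 1192, 2.39 and 1059 CPM in control and 276, 426 and 442 CPM with dexamethasone. At least 3 mast cell or basophil markers were found in 5, 0 and 1 control cells and 0, 9 and 1 dexamethasone cells. At least 2 of them, which Hdc and Il1rl1 alone can make up, were found in 7, 2 and 2 control cells and 14, 62 and 34 dexamethasone cells, and at least 3 at any count in 32 of 92 cells on dexamethasone day 2. At least 3 macrophage markers were found in 2, 1 and 1 control cells against 2, 0 and 5. For endothelial and stromal markers the numbers were 4, 0 and 0 against 0, 0 and 1. On day 1 looser rules turned this direction, with 6 control against 11 dexamethasone cells at any count. With at least 2 markers at 10 CPM they were 15 against 20. No cell reached 3 lymphoid or hepatocyte markers at 10 CPM. At any count 1 control day 1 cell and 1 dexamethasone day 2 cell reached 3 lymphoid markers. Camera made no call for dexamethasone on mast cell and basophil (median 0.94, adjusted p 0.128), neutrophil and monocyte (-0.66, 0.845), lymphoid (0.84, 0.73), macrophage (0.39, 0.496), hepatocyte (0.64, 0.368) or endothelial and stromal markers (-0.41, 0.696). Adjusted over the list alone, 2 of 6 mast cell and basophil markers and 2 of 5 hepatocyte markers rose.

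Across 20040 genes, the dexamethasone difference of 1 day was set against a control time difference from plates that shared no library with it. Pearson correlations were -0.014 for day 1, -0.112 for day 2 and -0.091 for day 3 (Spearman 0.041, -0.138 and -0.137). Dexamethasone differences of days 1 and 2, 1 and 3, and 2 and 3 had Pearson correlations of 0.080, 0.081 and 0.171 (Spearman 0.134, 0.1 and 0.229). Genes are not independent replicates, so no p is given. Over 4329 genes at a mean of at least 50 CPM the correlations with time were 0.054, -0.486 and -0.475 (Spearman 0.291, -0.374 and -0.483). Those between days were 0.459, 0.384 and 0.596 (Spearman 0.437, 0.285 and 0.61).

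For the genes named whatever their values, coordinates on GRCm38 follow the annotation and span the whole gene. Fkbp5 (ENSMUSG00000024222) lies on chromosome 17 from 28399094 to 28517527, Tsc22d3 (ENSMUSG00000031431) on chromosome X from 140539528 to 140600659 and Per1 (ENSMUSG00000020893) on chromosome 11 from 69095217 to 69109960. Zfp36l2 (ENSMUSG00000045817) lies on chromosome 17 from 84183931 to 84187947 and Nr3c1 (ENSMUSG00000024431) on chromosome 18 from 39410545 to 39519421. Kit (ENSMUSG00000005672) lies on chromosome 5 from 75574916 to 75656722, Gata2 (ENSMUSG00000015053) on chromosome 6 from 88193891 to 88207032 and Gata1 (ENSMUSG00000031162) on chromosome X from 7959260 to 7978071. Klf1 (ENSMUSG00000054191) lies on chromosome 8 from 84901928 to 84905291 and Epor (ENSMUSG00000006235) on chromosome 9 from 21958897 to 21963506. Hbb-bt (ENSMUSG00000073940) lies on chromosome 7 from 103812524 to 103813996 and Hba-a1 (ENSMUSG00000069919) on chromosome 11 from 32283511 to 32284465.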

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

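The tests of depth, of plates and cultures, of cells with Cpa3 and of splits over all genes were set after the result was seen; for the other lineage cells and the splits at 50 CPM only the expected outcome was written before the test was run, while the removal of cells and the filter themselves were chosen after the data had been seen.

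The median difference of some gene lists was at least 0.5 on 1 day and at most -0.5 on another, a size chosen after the data were seen, and the difference between days was not tested. For interferon response genes the median log2 difference with dexamethasone was -0.44 on day 1, -1.21 on day 2 and 0.52 on day 3. Values given below at the floor were taken without the prior count. Plates at 0 were set to 3 counts, and members with at most 3 counts in both plates were left out. For mast cell and basophil markers it was -0.71, 7.11 and -0.75, and 6.82 on day 2 with plates at 0 set to the floor, but 1.26, 5.83 and 2.42, positive on each day, without the cells with at least 2 neutrophil or monocyte markers, a removal also chosen after the data were seen. For neutrophil and monocyte markers it was -2.67, 5.88 and -2.16, and 5.62 on day 2 at the floor, where 9 of 14 members had no count on control day 2, and -0.98, 1.71 and -0.99 without those cells, over 8 members and after a removal by these same markers, which in part fixes the smaller size. For lymphoid markers it was -0.53, 1.91 and 0.62, and 2.28 on day 2 at the floor, and -0.18, 1.97 and 0.36 without those cells, where no day reaches -0.5. For macrophage markers it was -0.13, 0.61 and -0.90, and 0.26 on day 2 at the floor over 5 of the 6 members. Without those cells it was -0.87, -0.37 and -0.89 over 4 of the 6 members. The interferon response values without them were -0.23, -1.30 and 0.60.

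The lower erythroid progression score with dexamethasone on each day was the pattern weighed first. A difference in depth would shrink it in cells thinned to 620000 counts, and there the mean difference was -2.07. A share of cells of the neutrophil and monocyte lineage would shrink it once they are removed, and without them it was -2.18, so both are argued against as the whole cause. What stays open is a difference between plates, lanes or cultures, which cannot be told apart from dexamethasone with 1 plate per group. A slower progression under dexamethasone may be the biological candidate explanation and remains a hypothesis, which further plates of each group from separate cultures would test.

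Early progenitor genes stood at a median of -0.22 with dexamethasone on day 1 and higher on days 2 and 3. The control day 1 plate held 17 cells with neutrophil or monocyte markers, and without such cells on any plate the medians of days 1, 2 and 3 went from -0.22, 1.18 and 1.43 to 0.20, 0.74 and 0.02. The day 1 value is above 0, the bound written beforehand for those cells as the cause, but 14 members were higher and 8 lower with an SD of 1.20. The rule for reading members that go both ways was set around the time the value was seen. They go both ways here, so the removal leaves open whether those cells account for the sign on day 1 or for the day 3 value. The sign on day 1 also depends on the measure. In all kept cells, plate medians of the early progenitor part of the score per cell differed by 0.34, 1.33 and 1.07 on days 1, 2 and 3. The median cell was thus higher on day 1 as well, while the list median comes from sums over all cells of a plate.

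Il1rl1 and Gata2 were higher with dexamethasone on each day and Hdc on days 2 and 3. A few mast-cell-like cells with Cpa3 could carry such transcripts, but in the cells without a Cpa3 count the smallest daily log2 difference of these genes was 1.27, that of Gata2 on day 1. On day 2, 74.2% of the dexamethasone cells without Cpa3 had Hdc at 10 CPM or more, against 5.2% of control cells. Hdc stood at 211.6 CPM in the former and 2.8 CPM in the latter, so cells with Cpa3 do not account for all of the difference. The 211.6 CPM was well below the value of the whole dexamethasone plate. Cells with Cpa3 thus carried much of its Hdc counts. At least 3 mast cell or basophil markers at 10 CPM were found in 9 of 92 dexamethasone day 2 cells; a mast cell or basophil programme without Cpa3 was not tested, and a difference between plates stays open. A broad response to the hormone is a hypothesis, which further plates from separate cultures would test.

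For the number of genes called for dexamethasone, the 6 plates make 10 splits into groups of 3, too few for a share under 0.05. Over all genes the real split gave 0 and the highest other split gave 0. Any split gives at least 0, so the 10 of 10 that gave as many decide nothing. At a mean of at least 50 CPM the real split gave 39 and the highest other split 2, so 1 of 10 gave as many. Only 4 of the 10 splits, the real one among them, keep 1 plate of each day in each group, as the day term of the test needs, and the other 3 of these gave 0. Every split but the real one mixes control and dexamethasone plates. A dexamethasone difference would then add to the spread in its fit and lower its count. The low counts of these splits therefore cannot show what 39 would be without such a difference.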

How the results depend on the processing

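Filters on mean CPM for the number of genes, robust estimates and the removal of cells with neutrophil or monocyte markers were tried after the data had been seen. The number of genes called by edgeR for dexamethasone, day 3 and day 2 was 0 with RLE size factors, no filter on low counts, thinned cells, all wells, the stricter cell filter, no mitochondrially encoded genes, robust estimates, without the marked cells, and with each day left out where the contrast kept its days. For dexamethasone it was 0 without the day term as well, and the smallest adjusted p over the planned edgeR settings lay between 0.168 without day 3 and 0.893 without day 2. DESeq2 called 1258, 2061 and 1550 genes, and in simulated data it also called more unchanged genes (155 against 10). With genes at a mean of at least 5 CPM edgeR called 0, 183 and 7, at 10 CPM 0, 310 and 123, and at 50 CPM 39, 549 and 233. Fewer genes were tested (9525, 8284 and 4329), and the smallest adjusted p for dexamethasone was 0.0767, 0.0501 and 0.0247. The calls for dexamethasone thus depend on the filter and on the tool.

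At 50 CPM the correlations of the dexamethasone difference with time moved to 0.054, -0.486 and -0.475 and those between days to 0.459, 0.384 and 0.596, and without the marked cells that of days 1 and 2 was 0.134. The cause was not tested. With an estimated correlation between genes, 0 lists passed the threshold for dexamethasone and 0 for day 3 against day 1. That form of the test rests on the 2 residual degrees of freedom. The glucocorticoid receptor targets lost their dexamethasone call at an estimated correlation of -0.01, below the preset 0.01. For that list a lost call therefore does not show that correlation between genes had produced it. Several other lists had estimated correlations far above the preset, with 0.877 for G2 and M phase, 0.802 for S phase and 0.774 for globins. It was 0.562 for red cell membrane and late erythroid genes, 0.544 for MYC and ribosome biogenesis and 0.463 for heme and iron. Camera p-values of these lists at the preset correlation may therefore be far too small. The difference of the progression score stayed negative on each day, with a mean of -2.07 in thinned cells, -2.06 without globins, -2.15 with the stricter filter, -1.41 with a pseudocount of 10 CPM and -2.18 without the marked cells. With the pseudocount of 10 CPM the differences on days 1, 2 and 3 were -0.43, -2.05 and -1.74, so their size depends on the pseudocount.

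Of the fold changes of named genes over all settings 3144 kept direction and side of the threshold, 191 passed it in addition and 61, none of them called, had the other sign. For dexamethasone the sign turned in 12 named genes without day 1, 11 without day 2, 8 without day 3, 5 without the day term and 4 without the marked cells. These included genes with a main log2 fold change of a size up to 3.43 without day 1, 4.09 without the day term and 5.57 without the marked cells, so some large values rest on 1 day or on those cells. For day 3 against day 1 the sign turned in 8 named genes without the marked cells, with main sizes up to 4.53, in 4 in thinned cells and in 2 without day 2. Of the within-day ratios 146 stayed, 21 moved and 1 was reversed, that of Mpo on day 1 at 0.721 without the marked cells, which carry Mpo. Shares of cells with markers of other lineages moved in 35 of 84 cases with looser marker rules. No paired analysis was possible because a plate sum carries no number, and the numbers in the labels name the index pair of a well. This concerns the well numbers only, since the day term of the main test and the daily differences of the scores do pair the plates of a day. Depth limits low genes: a plate without a count allows up to 0.0335 CPM.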

Other observations

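The 4 most abundant genes of the glycolysis list stood highest on day 2 in both treatments. Aldoa, the aldolase of glycolysis, was at 1298, 3526 and 1280 CPM on control days 1, 2 and 3 and at 1504, 3256 and 1295 CPM with dexamethasone. Ldha, lactate dehydrogenase, was at 2370, 3657 and 1583 CPM and at 3181, 4150 and 1813 CPM, and Pkm, pyruvate kinase, at 592, 1429 and 560 CPM and at 810, 1808 and 618 CPM. Tpi1 was at 1033, 2129 and 775 CPM and at 1125, 1681 and 724 CPM. The day 2 plates were 1 per treatment, so this is a value of those plates.

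Slc40a1, which encodes the iron exporter ferroportin, was at 70.4, 64.5 and 71.9 CPM in control and at 27.1, 15.9 and 50.5 CPM with dexamethasone. Hmox1, the heme-degrading oxygenase, was at 3.14, 28.2 and 44.4 CPM in control and at 2.34, 15.9 and 12.1 CPM with dexamethasone. Both are on the macrophage list, while Cd68, a general macrophage marker, was at 9.24, 7.61 and 9.76 CPM against 10.4, 9.10 and 10.4 CPM. Bst2, an interferon-inducible membrane protein, was at 23.8, 15.6 and 16.5 CPM in control and at 30.01, 35.8 and 40.9 CPM with dexamethasone. Pdgfrb, a receptor for platelet-derived growth factor, was at 15.6, 8.82 and 5.03 CPM in control and at 15.4, 33.4 and 22.7 CPM with dexamethasone. None of these passed the edgeR threshold over all genes.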
